A study of Mus musculus with 2 samples.

How the data were processed

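The data are 2 single-cell RNA libraries of live CD45+ cells sorted from enzyme-digested mouse thoracic aorta, 1 from untreated C57BL/6 mice and 1 from Ldlr-/- mice on a high-fat diet (HFD). Each library pools 10 mice, and about 17400 cells were loaded for each with a 3' droplet kit that adds a 16 bp cell barcode and a 10 bp unique molecular identifier (UMI). The deposited matrices hold whole UMI counts per gene and barcode, which the authors made from the sequencing reads without further normalization. Cell Ranger, Seurat and the mm10 genome are named per the submitters' processing notes, with versions not given in the sources used here. The matrices list 27998 genes, of which 27722 (99.0%) were found by gene ID in GENCODE release M21 of GRCm38, the source of gene positions, lengths and types. The release used for the counts was not stated.

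Both libraries hold called barcodes only. The lowest barcode had 1601 UMIs in the C57BL/6 library and 2056 in the Ldlr-/- HFD library. Barcodes with at least 200 genes, at least 500 UMIs and at most 10% mitochondrial UMIs were kept, which left out 64 and 131 barcodes. Scrublet (scanpy 1.11.5, simulated doublet ratio 2, 30 neighbours) called 2 and 1 doublets by its automatic threshold, far under the expected 5.02% and 1.96%, so that call did not work. In its place the cells with the highest Scrublet scores were removed at 0.8% per 1000 barcodes in each library, 373 and 61 cells. This left 5840 and 2255 analysed cells.

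Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components, 20 neighbours and Leiden clustering at resolution 1 (leidenalg 0.10.2, python-igraph 0.11.9, seed 1) were computed over both libraries together, without integration. Cell cycle, dissociation, interferon, sex chromosome, haemoglobin, mitochondrial, ribosomal protein and antigen receptor variable genes were not used as variable genes. Clusters of at least 40 cells that held markers of several classes were split again at resolution 1 with 15 components. Markers of 26 classes, 25 gene lists, the rule for named genes, the comparisons and most alternatives were chosen before the data were examined. The scoring of clusters was set after the clusters were seen. A cluster took a class outside the macrophages on at least 3 of the class's markers. Each needed a log2 level of 2 or more over all other cells and detection in at least 10% of the cluster's cells. The cluster could not hold more intimal macrophage markers at that level than markers of the class. It was macrophage-like where the mean log2 level of the macrophage markers was at least -1.5, intimal-like with at least 3 intimal markers at that level, adventitial-like with a mean of the adventitial markers of at least -1, and otherwise other macrophage-like. A name was dropped where the 10 genes with the highest fold held more markers of another class than of its own. Clusters 6, 15 and 16 stayed other macrophage-like. That remainder was not compared gene by gene, because it has no markers of its own and different clusters hold it in each library. Sub-cluster 11g stayed unnamed. Names end in "-like" because they rest on RNA alone.

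With 1 library per group there was no test, and cells were not treated as replicates. Shares have exact Clopper-Pearson 95% intervals. Where a count was 0, the limit is that of 3 counts. UMIs were summed over the cells of a class in each library and given as counts per 1000000 UMIs of the class (CPM), with exact Poisson 95% intervals. Ratios of CPM have the exact conditional binomial 95% interval of the ratio of 2 Poisson counts. All these intervals cover counting error only. Ratios against a count of 0 use 3 counts in its place and are given as bounds. Such a bound is not the limit of a 95% interval. A list's value is the median log2 ratio of its members with at least 20 UMIs over both libraries. Its percentile is among 10000 random lists of the same size, matched on mean expression in 20 bins, and describes these libraries only. The interval of a list's median is the exact order-statistic interval over its members.

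Of the 25 lists, 18 were compared: lipid uptake and storage, cholesterol efflux and LXR targets, cholesterol synthesis, foamy macrophage genes, lysosome, NF-kB and inflammatory cytokines, type I interferon response, major histocompatibility complex (MHC) class II presentation, S phase, G2 and M phase, dissociation and immediate early genes, complement, extracellular proteinases and their inhibitors, glycolysis, oxidative phosphorylation, mitochondrial transcripts, efferocytosis, and chemokine receptors and recruitment. Lists were compared in classes with at least 50 cells in each library, which were macrophage-like cells, their intimal-like and adventitial-like subsets, and conventional dendritic cell-like cells. The T cell and B cell lists gave no result, because no T cell or B cell class had 50 cells in both libraries. The sex chromosome, genotype and haemoglobin lists served as checks. Naming markers were left out of the lists when the subsets were compared within a library.

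Named genes in macrophage-like cells are the 12 with the highest and the 12 with the lowest CPM ratio among genes with at least 100 UMIs over both libraries and detected in at least 5% of the class's cells in at least 1 library. Mitochondrial, ribosomal protein, haemoglobin, antigen receptor, sex chromosome, Gm-named and Rik-named genes were left out of that ranking. The other classes have 5 on each side, and each list up to 4 members with the largest absolute log2 ratio and at least 50 UMIs. For intimal-like over adventitial-like cells, the 10 highest and 10 lowest genes lie on the same side in both libraries and were ranked by the smaller absolute log2 ratio. Cycling cells had UMIs of at least 2 different genes of the G2 and M phase list after every cell was thinned to 3600 UMIs, with shallower cells left out.

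Alternatives were a stricter cell filter (at least 500 genes, at least 1000 UMIs, at most 5% mitochondrial UMIs), no removal by Scrublet score, Leiden resolution 2, each library clustered alone, lipid and lysosome lists left out of the variable genes, TMM scaling (edgeR 4.0.16, R 4.3.3), every cell thinned, means over cells, list members from 5 UMIs, named genes from 300 UMIs, and for cycling at least 3 genes, at least 1 UMI of Mki67 or Top2a, or unthinned counts. A value counts as moved when it lies outside its own 95% interval. It counts as reversed when its sign turned, for a list outside the central 95% of random lists or a gene whose interval excluded a ratio of 1. The intervals and the list percentiles were tested on counts simulated from the gene totals of all barcodes at the sizes of the 2 libraries, with 13897 eligible genes. The counts were drawn from Poisson distributions, the model behind the intervals, without a gene length trend or spread between cells. The simulation therefore tests the calculation only, not how well the intervals cover real spread. Intervals held the simulated ratio for 95.6% of 13697 genes with no difference and for 92% to 98% of 50 genes at each of 4 other ratios. Of 200 simulated lists with no difference, 14 fell outside the central 95%, and all 10 doubled lists lay above percentile 97.5. Work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0, and figures were drawn with matplotlib 3.10.9.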

Results

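Gene expression was measured in single live CD45+ cells, the marker of leukocytes, sorted from digested thoracic aortas of mice. One library came from 10 untreated C57BL/6 mice aged 8 weeks. The other came from 10 mice that lack the low-density lipoprotein receptor (Ldlr-/-) and carry a Cx3cr1 cre driver with a tomato reporter. These mice received tamoxifen at 8 weeks of age and a high-fat diet (HFD) for 21 days from 11 weeks. The C57BL/6 library held 6277 barcodes and 44418462 UMIs, with a median of 6673 UMIs and 2109 genes per barcode. The Ldlr-/- HFD library held 2447 barcodes and 20405639 UMIs, with a median of 7174 UMIs and 2527 genes. After filtering, 5840 and 2255 cells were analysed, with medians of 6646 and 7404 UMIs. There is 1 library per group, so the difference has no replicate check, and genotype, diet, age, tamoxifen and library preparation all differ together. All positions are in GRCm38.

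Ldlr, the knocked-out gene (ENSMUSG00000032193, chromosome 9, 21723483 to 21749919), gave 708 UMIs in macrophage-like cells of the C57BL/6 library, 18.2 CPM (95% interval 16.9 to 19.6). In the Ldlr-/- HFD library it gave 19 UMIs, 1.33 CPM (0.801 to 2.08). A 3' tag can lie outside the disrupted part of a gene, so the remaining UMIs do not show an intact transcript. Cx3cr1, which carries the cre knock-in on 1 allele, was at 145 CPM in the C57BL/6 library and 330 CPM in the other (ratio 2.28, 2.19 to 2.37). Both libraries carried Y-linked transcripts, with Ddx3y at 54.8 and 73.1 CPM, Eif2s3y at 40.9 and 33.3, Kdm5d at 6.67 and 18.8, and Uty at 13 and 27.3. Xist, which marks female cells, gave 1 UMI in macrophage-like cells of the C57BL/6 library and 0 in those of the other, a limit of 0.210 CPM, and its antisense transcript Tsix gave 0 in both.

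The first question was which leukocytes the aorta held in the healthy and in the early atherosclerotic state. Macrophage-like cells made up most of both libraries, 96.7% (96.2 to 97.1) of C57BL/6 cells and 77.9% (76.1 to 79.6) of Ldlr-/- HFD cells. Lymphoid-like cells were 0.205% (0.106 to 0.359, 12 cells) and 9.27% (8.10 to 10.5, 209 cells), of which 11 and 184 were T cell-like and 1 and 25 were like group 2 innate lymphoid cells. T cell-like sub-clusters 14a (1 and 34 cells), 14b (1 and 30 cells) and 14c (2 and 35 cells) also carried macrophage transcripts, at mean log2 levels of -0.41, -0.37 and -0.89 against all other cells, above the limit of -1.5 for a macrophage name. Clusters 14d (1 and 25 cells) and 20 (3 and 68 cells), at levels of -3.27 and -3.48, made up 4.12% (3.34 to 5.03) of the Ldlr-/- HFD library, and T cell-like sub-cluster 14e (4 and 17 cells) lay between, at -1.96. Sub-cluster 14c was led by Gzma, Nkg7 and Klre1, with as many natural killer (NK) cell as T cell markers among its 10 highest genes, and at Leiden resolution 2 a cluster with these leading genes was named NK cell-like (2 and 36 cells). Classical monocyte-like cells, the blood-derived precursors of macrophages, were 0.274% (0.157 to 0.445) and 1.82% (1.31 to 2.46, with 1.02% with each library clustered alone and 1.11% with lipid and lysosome lists left out of the variable genes). These cells also carried macrophage transcripts above the limit of -1.5. Sub-cluster 11a (0 and 29 cells, median 12149 UMIs) lay at -0.70 and 11b (16 and 12 cells) at -1.43. The higher share of the Ldlr-/- HFD library thus rests mostly on 11a. Conventional dendritic cell-like cells, which present antigen to T cells, were 1.58% (1.27 to 1.93) and 3.06% (2.39 to 3.86), with 44 and 34 cells of the cDC1-like type and 48 and 35 of the cDC2-like type. Mast cell-like cells were 0.103% (0.0377 to 0.224, 6 cells) and 0.665% (0.373 to 1.10, 15 cells), and numbered 14 and 18 with each library clustered alone. Although the sort was for CD45, non-leukocyte-like cells were 1.16% (0.905 to 1.47) and 5.68% (4.76 to 6.71), made up of 30 and 57 fibroblast-like, 3 and 55 endothelial-like and 35 and 16 smooth muscle-like cells. With the stricter cell filter, non-leukocyte-like cells were 0.729% and 4.44%. No B cell-like or neutrophil-like cluster was named in the main clustering, but a B cell-like cluster was at Leiden resolution 2 (1 and 21 cells), and with the Ldlr-/- HFD library clustered alone a B cell-like (22 cells) and a neutrophil-like cluster (20 cells) were. Non-classical monocyte-like clusters were also named only in alternatives. These were Leiden resolution 2 (1 and 41 cells), lipid and lysosome lists left out (2 and 22, and 0 and 23 cells) and the Ldlr-/- HFD library alone (26 cells). The cluster at resolution 2 shared leading genes such as Itgal, Fgr and F10 with unnamed sub-cluster 11g. Shares depend on the sort and digestion of each library, and with each library clustered alone no lymphoid-like or monocyte-like cluster was named in the C57BL/6 library.

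**Figure D1:**
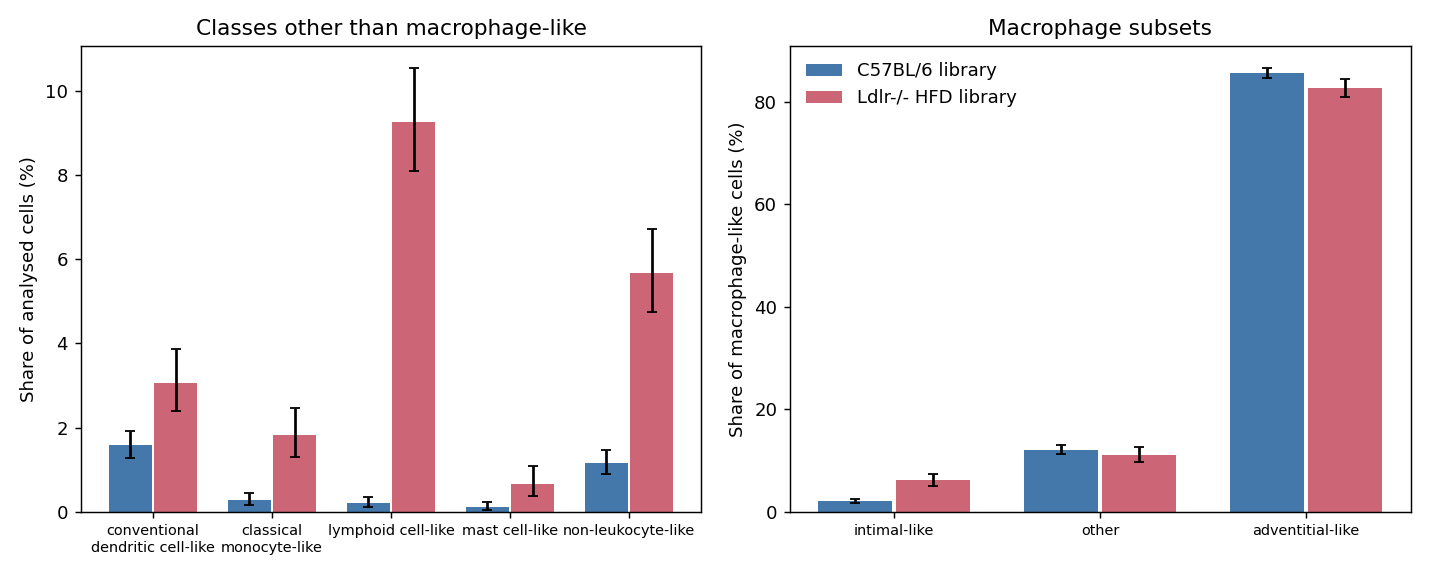
Shares of cell classes other than macrophage-like among all analysed cells (left, %) and of the macrophage subsets among macrophage-like cells (right, %), with blue bars for the C57BL/6 library and red bars for the Ldlr-/- HFD library and exact 95% intervals as error bars. Lymphoid-like cells stand at 0.205% and 9.27%, and intimal-like macrophages at 2.14% and 6.15%.

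Macrophages of the aortic intima, the layer where plaques form, were set against those of the adventitia, the outer layer, to ask how each subset is represented in the healthy and the early diseased aorta. Intimal-like cells, named from Itgax, Acp5, Mmp12 and similar markers, were 121 of 5646 macrophage-like cells of the C57BL/6 library, 2.14% (1.78 to 2.56). They were 108 of 1756 in the Ldlr-/- HFD library, 6.15% (5.07 to 7.38). Adventitial-like cells, named from Lyve1, Folr2, F13a1 and similar markers, were 85.7% (84.8 to 86.6) and 82.7% (80.9 to 84.5). Their marker mean was taken against all analysed cells, most of them macrophage-like, so the name also covers clusters below that average. Clusters 1, 2 and 12 lay at -0.18, -0.12 and -0.88. The remaining 12.1% (11.3 to 13.01) and 11.1% (9.67 to 12.7) met neither naming rule and sat in clusters 6, 15 and 16. In the C57BL/6 library this remainder was 5.05% at Leiden resolution 2. In the Ldlr-/- HFD library it was 4.52% with lipid and lysosome lists left out of the variable genes. Clusters 6 (616 and 8 cells) and 15 (67 and 69 cells) lay near the adventitial threshold of -1, at -1.29 and -1.37, and with a threshold of -1.5 the remainder was 0.0354% and 6.72% and the adventitial-like share 97.8% and 87.1%. Cluster 16 (2 and 118 cells), with an adventitial mean of -2.11, had 2 intimal markers at the level asked for, against the limit of 3. The intimal-like share of the Ldlr-/- HFD library thus depends on that limit.

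The 2 libraries hardly shared clusters within these subsets, and a cluster mostly of 1 library may be that library, not a type. Intimal-like cells of the C57BL/6 library sat in sub-clusters 13a (60 cells) and 13b (59 cells). Those of the Ldlr-/- HFD library sat in 13c (34 cells) and in 11d, 11e and 11f (19, 11 and 41 cells), which held no C57BL/6 cell. Sub-cluster 13c also had 3 non-classical monocyte markers at the level asked for, but was named intimal-like because 6 intimal markers reached it. In 11d to 11f together, Gpnmb stood at 1976 CPM and Fabp5 at 4838 CPM, against 18.7 and 32.1 CPM in cluster 13 of the same library, so these 71 cells carried a foamy profile, that of lipid-laden macrophages. Their median of 16293 UMIs was above the library's, and doublets are not excluded among them, because the automatic Scrublet call did not work. Without these cells the intimal-like share of the Ldlr-/- HFD library was 2.20%. Adventitial-like cells filled clusters 1, 3, 4, 5, 7, 8 and 10 in the C57BL/6 library and clusters 2 (928 cells) and 9 (453 cells) in the other, with cluster 12 in both (121 and 51 cells).

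To ask how macrophages differed between the healthy and the early diseased aorta, genes were compared over all macrophage-like cells (38976406 and 14273404 UMIs). Genes of lipid handling and foamy cells were among the highest in the Ldlr-/- HFD library. Gpnmb, a glycoprotein of lipid-laden and lysosome-stressed macrophages (ENSMUSG00000029816, chromosome 6, 49036546 to 49070929), was at 0.641 and 180 CPM, a ratio of 281 (190 to 435). Fabp5, a fatty acid-binding protein (ENSMUSG00000027533, chromosome 3, 10012548 to 10016607), was at 8.31 and 461 CPM (ratio 55.5, 49.6 to 62.2). Abcg1, a cholesterol exporter, was at 5.88 and 86.5 CPM (14.7, 12.8 to 17.0), and the desaturase gene Scd2 was 13.9-fold higher. Cd300lf, a receptor for lipids of dying cells, was 19.1-fold higher. Without 11d to 11f the log2 ratio was 3.99 for Gpnmb (8.13 with them), 2.49 for Fabp5 (5.79), 3.24 for Abcg1 (3.88), 2.66 for Scd2 (3.79) and 2.93 for Cd300lf (4.26). Genes of acute inflammation and stress were among the lowest: the neutrophil chemokine Cxcl2 (ENSMUSG00000058427, chromosome 5, 90903871 to 90905938) was at 4166 and 324 CPM, 12.9-fold lower (12.5 to 13.3) in the Ldlr-/- HFD library.

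The other genes with the highest ratios were Ptprb, a receptor phosphatase best known from endothelium (150, 97.53 to 243), Cacna1a, a calcium channel subunit (53.4, 41.4 to 69.9), Il7r, the interleukin 7 receptor (33.3; log2 5.06, and 3.94 without 11d to 11f), B3gat2 (31.5), Hspb7 (19.4), Plac8 (15.3) and Zdhhc2 (14.6). Transcripts of other leukocytes stood higher in the same cells: Cd3e of T cells was at 0.0257 and 3.29 CPM and Ly6c2 of monocytes at 0.308 and 8.83, while Il7r stood at 21.4 CPM in these cells and 295 in lymphoid-like cells of the Ldlr-/- HFD library. Ptprb was at 80.7 CPM in macrophage-like cells of that library and at 86.3 and 89.8 CPM in its dendritic and lymphoid-like cells, and at 2421 CPM in its endothelial-like cells, while Cdh5 of endothelium was at 1.33 CPM in its macrophage-like cells. The genes with the lowest ratios were Fam71a (3 UMIs in the Ldlr-/- HFD library, 120-fold lower, 41.0 to 583), Tmem88 (108-fold, 52.5 to 270), Maff (30.7), Ciart (24.9), Gem (23.0), Ccdc85b (20.6), the niacin receptor Hcar2 (20.3), Gadd45b (18.6), Gdf15 (14.5), Ldlr itself (13.6) and the histone demethylase Kdm6b (12.99). With at least 300 UMIs asked of a gene, 7 of the 12 highest and all 12 of the lowest stayed in the ranking.

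Genes of cholesterol export and of cholesterol synthesis stood on opposite sides. Of 13 measured genes of cholesterol efflux and LXR targets, 10 were higher in the Ldlr-/- HFD library, with a median log2 ratio of 1.31 (percentile 100 among 10000 random lists; 0.75 without 11d to 11f). Scd1 was 18.7-fold and Apoc1, an apolipoprotein, 10.3-fold higher (log2 4.23 and 3.37, and 3.39 and 1.67 without 11d to 11f). Of 20 genes of cholesterol synthesis, 16 were lower (median -0.56, percentile 0), among them Insig1, which restrains the pathway (103 and 28.0 CPM, 3.66-fold lower), Sqle (2.44), Fdps (2.33) and Mvd (2.08). Lipid uptake and storage genes were higher for 13 of 15 (median 0.65, percentile 98.0), including Soat1, which makes cholesteryl esters (3.37), Fabp4 (5.67) and Cd5l (6.01). Foamy macrophage genes were higher for 14 of 20 (median 0.42, percentile 98.4), led after Gpnmb and Fabp5 by Spp1 (10.6) and Syngr1 (7.27), and at a median of 0.11 without the 5 that also served to name the intimal subset. Without 11d to 11f the foamy list stood at 0.18, and the log2 ratios were 0.25 for Fabp4, 0.11 for Cd5l, 2.06 for Spp1 and 0.65 for Syngr1. Lysosome genes went both ways, 9 of 27 higher (median -0.20, percentile 1.69), with the proton pump subunits Atp6v0d2 2.71-fold higher and Atp6v0c 2.91-fold lower, Gla 2.45-fold lower and the cholesterol transporter Npc1 2.48-fold higher. Without 11d to 11f the log2 ratio was 0.10 for Atp6v0d2 (1.44 with them) and -2.12 for Gla (-1.29).

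Inflammatory genes were lower. Of 20 NF-kB and cytokine genes, 18 were lower in the Ldlr-/- HFD library (median -1.82, percentile 0), among them Il6 (7.51-fold), Il10 (7.28) and Ccl3 (6.80). All 24 dissociation and immediate early genes, which respond to tissue digestion, were lower as well (median -1.63, percentile 0), with Ier3 10.7-fold, Socs3 9.79-fold, Hspa1a 7.96-fold (4222 and 530 CPM) and Hspb1 7.02-fold lower. Type I interferon genes were lower for 14 of 22 (median -0.36, percentile 0), including Cxcl10 (8.95), Ifit1 (4.05), Oasl1 (3.76) and Isg15 (3.28). Glycolysis genes were lower for 13 of 18 (median -0.37, percentile 0), with Eno1 4.19-fold, Hk2 2.74-fold, Gpi1 1.82-fold and Pfkfb3 1.74-fold lower. Complement genes were lower for 7 of 11 (median -0.28, percentile 4.82), with C2 2.31-fold and C1qb 1.76-fold lower and C3 1.65-fold higher.

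Extracellular proteinases and their inhibitors, which remodel matrix, were higher for 15 of 17 genes (median 1.30, percentile 99.99), with Mmp14 6.26-fold, Ctsk 6.14-fold, Timp3 4.79-fold and Mmp8 4.10-fold higher, although without 11d to 11f the log2 ratio was -1.29 for Mmp8, 0.72 for Ctsk and 1.06 for Mmp14. Mitochondrial transcripts were higher for 12 of 13 (median 0.63, percentile 99.99), with mt-Nd6 3.41-fold, mt-Atp8 2.21-fold and mt-Co3 1.57-fold higher. This was not particular to macrophage-like cells, since the list stood at 0.76 in conventional dendritic cell-like cells. Over all barcodes of each library, the median mitochondrial share was 2.17% in the C57BL/6 library and 3.19% in the other. Efferocytosis genes, for the uptake of dead cells, were higher for 8 of 13 (median 0.56, percentile 94.3), among them Mertk (2.44), Itgav (2.31) and Axl (1.84). Genes of S phase were higher for 16 of 23 (median 0.44, percentile 71.5), such as Lig1 (3.24). TMM scaling shifts every log2 ratio of this comparison by -0.40, and it turns the direction of 4 lists. These are G2 and M phase genes (22 of 28 higher, median 0.35, percentile 47.8; -0.05 with TMM; Top2a 3.16-fold higher), chemokine receptors and recruitment (10 of 16, 0.23, percentile 74.96; -0.17; Ccr2 4.68, Itgal 3.94, Ccr1 2.83), oxidative phosphorylation (25 of 32, 0.20, percentile 97.8; -0.20; Ndufa1 1.54) and MHC class II presentation (7 of 12, 0.15, percentile 66.5; -0.26; Ciita 2.63 and Ctss 1.79-fold higher, Cd86 1.80-fold lower). The median over all genes was 0.33, and genes differed by length: the median log2 ratio was -0.00 among genes of up to 8893 bp and 0.73 among those of at least 50716 bp.

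**Figure D2:**
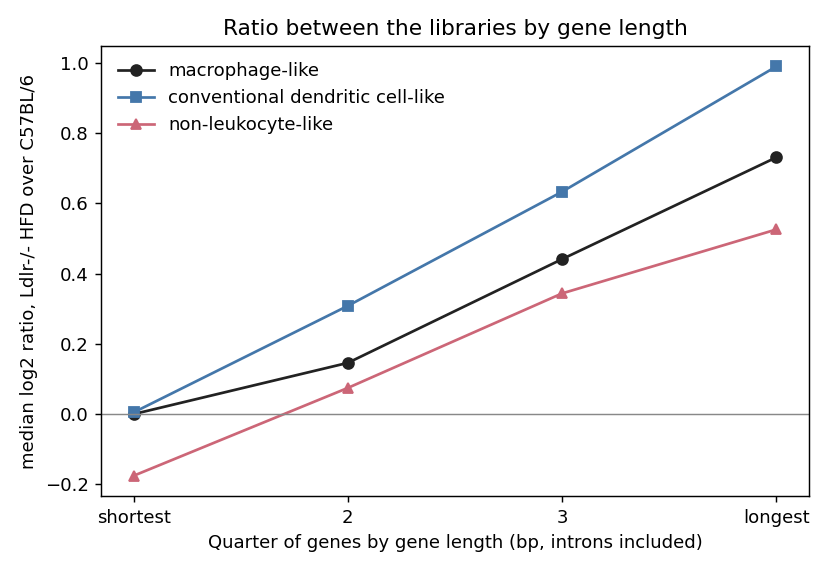
Median log2 ratio, Ldlr-/- HFD library over C57BL/6 library (y axis), in 4 equal groups of genes from the shortest to the longest (x axis, gene length in bp with introns), with a line for macrophage-like, conventional dendritic cell-like and non-leukocyte-like cells each. The longest genes lie above the shortest by 0.73, 0.99 and 0.70.

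**Figure D3:**
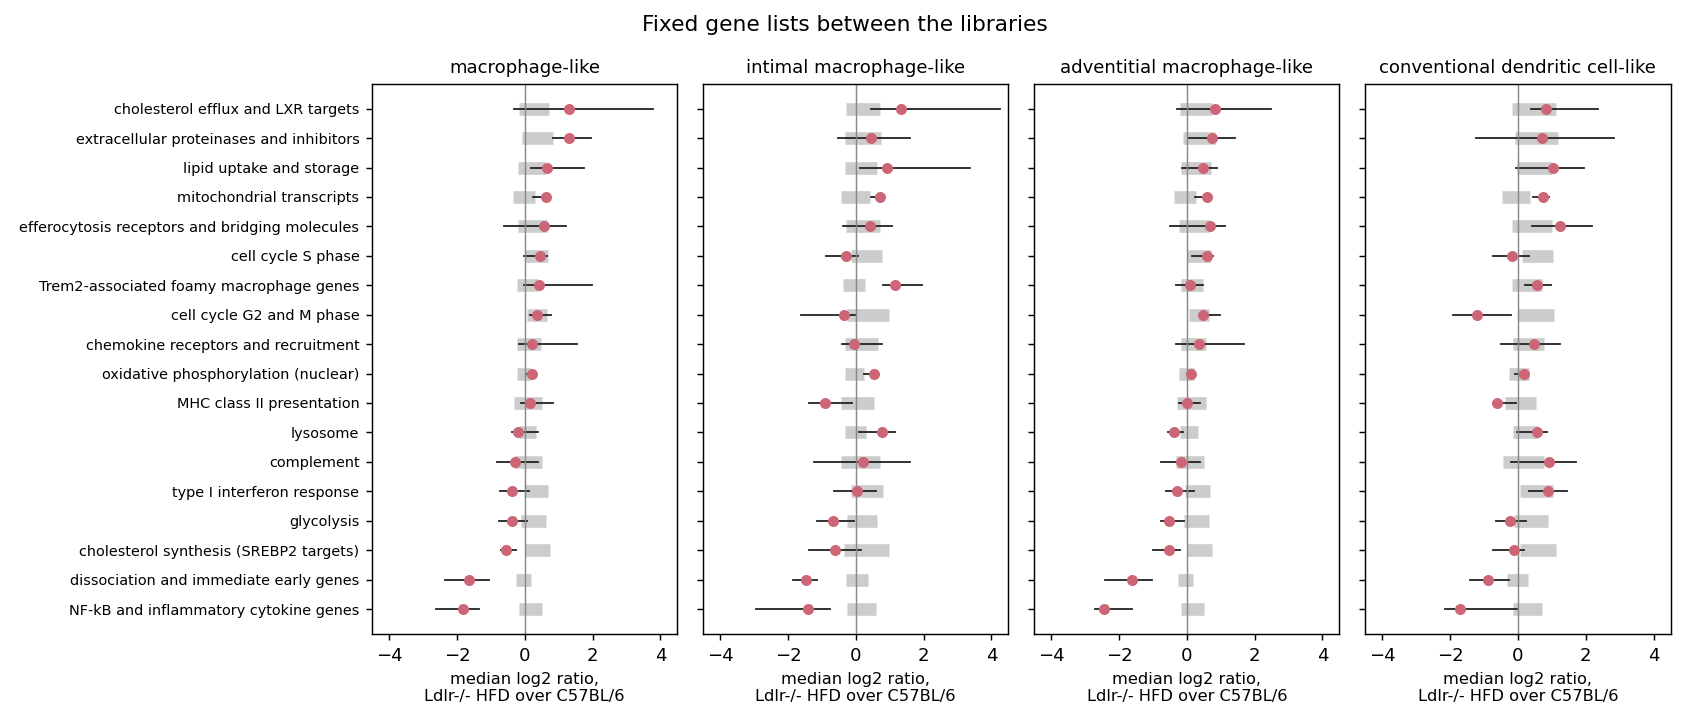
Median log2 ratio of each fixed gene list, Ldlr-/- HFD library over C57BL/6 library (x axis), in 4 classes (panels), with red points for medians, thin lines for their 95% order-statistic intervals over members and grey bars for the central 95% of 10000 random lists matched on mean expression. NF-kB and dissociation genes lie left of the grey bars in every panel, while TMM scaling would move the points of the macrophage-like panel by -0.40 and turn the 4 lists of G2 and M phase, chemokine receptors, oxidative phosphorylation and MHC class II there.

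Within intimal-like cells (1084631 UMIs and 1608755 UMIs), lipid and lysosome genes were higher and antigen presentation genes lower in the Ldlr-/- HFD library. Without 11d to 11f, however, the median log2 ratio was 0.32 for lipid uptake, -0.15 for lysosome and -0.11 for MHC class II genes. Gpnmb, with 2 UMIs in the C57BL/6 library, was 825-fold higher (228 to 6815), Fabp5 224-fold (142 to 379), Fabp4 at least 54.2-fold, Atp6v0d2 109-fold (1 UMI, 19.2 to 4314) and Ptprb 78.9-fold (1 UMI, 13.9 to 3142). Gpnmb and Atp6v0d2 are among the markers that named the intimal-like cells, 11d to 11f included, so their ratios partly follow from the naming. The lowest ratios were those of Cxcl1 (15.3-fold lower), Cxcl2 (14.6), the transcription regulator Id3 (12.4), Tmem119 (9.69) and Hspa1a (9.42). With at least 300 UMIs asked of a gene, 2 of the 5 highest and 3 of the 5 lowest stayed in the ranking. Lipid uptake genes were higher for 14 of 14 (median 0.93, percentile 99.9), with Soat1 6.34-fold and Lrp1 2.94-fold higher. Efflux genes were higher for 11 of 13 (1.34, percentile 100), with Abca1 7.83-fold and Apoc1 at least 20.2-fold higher. Foamy genes were higher for 15 of 20 (1.15, percentile 100) and lysosome genes for 20 of 27 (0.76, percentile 100), with Syngr1 20.8-fold and the protease Ctsd 3.88-fold higher. Of 12 MHC class II genes, 10 were lower (-0.91, percentile 0.01), such as H2-Eb1 (2.74-fold), Cd74 (2.60) and Cd86 (2.98). NF-kB genes were lower for 15 of 17 (-1.41, percentile 0), such as Il1b (8.01), and dissociation genes for 24 of 24 (-1.46, percentile 0).

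Glycolysis genes were also lower for 13 of 16 in intimal-like cells (-0.67, percentile 0.01), and cholesterol synthesis genes for 8 of 10 (-0.60, percentile 0.29). Oxidative phosphorylation (29 of 32 higher, 0.53, percentile 100) and mitochondrial transcripts (13 of 13, 0.70, percentile 99.8) were higher. Proteinases were higher for 10 of 13 (0.46, percentile 83.0), yet Mmp13 was 7.20-fold and Mmp12 2.40-fold lower. Efferocytosis genes were at 0.41 (8 of 12 higher, percentile 78.7), with Mertk 4.05-fold higher, and chemokine genes at -0.05 (7 of 15 higher, percentile 18.9). Complement (5 of 9 higher, 0.21, percentile 62.1) and interferon genes (10 of 18, 0.05, percentile 13.04) turned to -0.02 and -0.18 with TMM scaling, which shifts this comparison by -0.23, and to -0.30 and -0.48 without 11d to 11f, where chemokine genes stood at 0.20. Much of this difference lay in 11d to 11f: without them the foamy list stood at -0.06, the lysosome list at -0.15, MHC class II at -0.11, oxidative phosphorylation at 0.05, lipid uptake at 0.32, efflux at 0.54 and cholesterol synthesis at -1.19, with log2 ratios of 0.95 for Fabp5, -0.58 for Ctsd, -0.32 for H2-Eb1, -0.15 for Cd74, -0.78 for Cd86, 1.59 for Soat1, 0.84 for Lrp1, -1.69 for Il1b, -2.23 for Id3, -1.62 for Tmem119, -0.97 for Mmp13 and -0.27 for Mmp12. In cluster 13 alone Gpnmb was 10.1-fold higher (2 and 7 UMIs, 1.93 to 100), Atp6v0d2 11.6-fold (1 and 4 UMIs, 1.15 to 571) and Mertk 2.81-fold (1.64 to 4.79). Apoc1 had 0 and 3 UMIs, with a lower interval limit of 1.20-fold, Fabp4 had 0 and 1 UMIs and Syngr1 7 and 0. Ptprb stayed at 84.1-fold (13.9 to 3435) and Abca1 at 6.05-fold (4.38 to 8.45). With the lipid and lysosome lists left out of the variable genes, intimal-like NF-kB genes stood at -0.55. The S phase list (-0.28, percentile 0.56) and the G2 and M phase list (-0.36, percentile 1.10) had 6 of 19 and 2 of 12 genes higher, and stood at 0.22 and 1.11 without 11d to 11f and at 0.09 and 1.26 with every cell thinned.

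Adventitial-like cells had lower inflammatory genes and higher efflux genes in the Ldlr-/- HFD library, with foamy genes near 0. NF-kB genes were lower for 17 of 20 (median -2.45, percentile 0), with Cxcl2 19.0-fold, Cxcl1 10.2-fold and Ccl4 8.53-fold lower, and dissociation genes for 24 of 24 (-1.62, percentile 0). Efflux genes were higher for 10 of 13 (0.82, percentile 98.7), with Abcg1 13.6-fold and Abca1 2.64-fold higher, and cholesterol synthesis genes lower for 15 of 20 (-0.54, percentile 0). Foamy genes stood at 0.10 (percentile 44.7; -0.30 with TMM), although Gpnmb was still 15.9-fold higher (9.50 to 28.0). Lysosome genes were lower for 20 of 27 (-0.38, percentile 0.02), with Gla 4.84-fold lower, glycolysis genes for 14 of 18 (-0.52, percentile 0) and interferon genes for 13 of 22 (-0.29, percentile 0.03). The highest ratios were those of Ptprb (157), Cacna1a (51.4), B3gat2 (38.05), Hspb7 (22.3) and Zdhhc2 (21.7), and the lowest those of Fam71a (258-fold lower, 1 UMI, 46.2 to 10196), Tmem88 (187, 3 UMIs, 64.0 to 910), Maff (39.96), Ccdc85b (31.3) and Gadd45b (28.5). With at least 300 UMIs, 2 of the 5 highest and all 5 of the lowest stayed.

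Among the other lists in adventitial-like cells, efferocytosis genes stood at 0.68 (percentile 98.1), proteinases at 0.75 (percentile 94.8), mitochondrial transcripts at 0.60 (percentile 99.9) and lipid uptake at 0.49 (percentile 87.1), with Mertk 2.46-fold, Timp3 5.31-fold and Soat1 2.39-fold higher. S phase genes stood at 0.59 (18 of 23 higher, percentile 90.4) and G2 and M phase genes at 0.47 (26 of 28, percentile 76.4), with Lig1 3.55-fold and Top2a 3.65-fold higher, while at Leiden resolution 2 both Top2a (log2 -0.39) and the G2 and M phase list (-1.09) were lower. Complement stood at -0.17 (percentile 18.0). Chemokine genes (0.35, percentile 84.3), oxidative phosphorylation (0.13, percentile 90.6) and MHC class II (0.01, percentile 34.7) turned to -0.05, -0.27 and -0.39 with TMM, which shifts this comparison by -0.40 as well.

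To ask what sets intimal from adventitial macrophages apart from disease, the subsets were compared within each library, leaving out the genes that named them. Antigen presentation genes were higher in intimal-like cells of both libraries: 12 of 12 MHC class II genes in the C57BL/6 library (median log2 ratio 2.00) and 11 of 12 in the other (1.10), each above the random lists (percentile 100). Without 11d to 11f the latter median was 1.77. The genes with the highest ratios in both libraries were H2-M2 (340 and 656, the latter with 2 UMIs, 179 to 5457), the signalling genes Gngt2 (98.2 and 58.5) and Abi3 (118 and 40.2), the adhesion molecule Cadm1 (103 and 32.6), Rgs1 (18.4 and 18.3), Bcl2a1a (47.5 and 15.1), the lectin Lgals3 (13.4 and 26.7), Amz1 (14.7 and 12.7), Tmem51 (11.9 and 12.5) and lipoprotein lipase Lpl (11.9 and 18.8). Genes higher in adventitial-like cells included Slc9a3r2 (16.2 with 2 UMIs, and 9.94), Cd209d (7.84 and 11.3), the endothelin receptor Ednrb (11.9 and 6.55), the water channel Aqp1 (10.0 and 5.99), the ficolin Fcna (8.45 and 5.78) and the chemokine Cxcl12 (11.1 with 2 UMIs, and 5.75). The other 4 were Spats2l, Plekhg5, Ptk2 and Arhgap23, at 6.16 to 13-fold in the C57BL/6 library and 5.90 to 6.99-fold in the other, and Arhgap23 (1 UMI) lost its direction with every cell thinned (log2 0.08). Of the 10 genes on each side, 4 and 5 stayed with at least 300 UMIs.

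Interferon genes were higher in adventitial-like cells of both libraries (intimal over adventitial -1.11 and -0.79, percentile 0 in both), as were complement genes (-2.10 and -1.25, percentile 0 in both) and dissociation genes (-0.98 and -0.86, percentile 0 in both). Efflux genes were higher in intimal-like cells (1.00 and 0.81, percentile 99.99 and 100), as were lipid uptake (0.44 and 1.09, percentile 99.3 and 100) and the foamy list (0.47 and 1.56, percentile 99.6 and 100). Proteinases went both ways, with 7 and 6 of 11 genes higher in intimal-like cells (0.42 and 0.42, percentile 93.7 and 99.7; -0.07 in the Ldlr-/- HFD library clustered alone). The foamy value of the Ldlr-/- HFD library was 0.11 without 11d to 11f, its lipid uptake value 0.19 and its lysosome value 0.04 (0.76 with them, -0.14 in the C57BL/6 library). NF-kB genes stood at -0.47 and -0.48, cholesterol synthesis at -0.25 and -0.52 (0.02 in the latter with every cell thinned), glycolysis at 0.27 and 0.07, oxidative phosphorylation at -0.02 and 0.30 (-0.09 in the latter without 11d to 11f), mitochondrial transcripts at -0.08 and -0.04, efferocytosis at -0.06 and -0.10, and chemokine genes at 0.51 and -0.05. G2 and M phase genes stood at -0.67 and -1.91, but at -0.13 and -0.99 with every cell thinned, and in the Ldlr-/- HFD library at -0.20 at Leiden resolution 2 and -0.06 without 11d to 11f. Cluster 12, led by cell cycle genes, counted as adventitial-like here, so this contrast depends partly on its naming. S phase genes stood at 0.40 and -0.47, and in the Ldlr-/- HFD library at -0.20 at Leiden resolution 2, -0.05 with means over cells and 0.24 without 11d to 11f. TMM shifts these comparisons by 0.05 and 0.12, which turns only values nearer to 0 than that. Across 7405 genes, which are not independent replicates, 5153 (69.6%) lay on the same side in both libraries (Pearson r = 0.68). Cells of both libraries were clustered together and named by the same rule, so part of this agreement may follow from the grouping.

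Proliferation was compared because the series asks how far resident macrophages of the intima divide. After thinning, 8.78% (8.01 to 9.59, 447 of 5094) of macrophage-like cells of the C57BL/6 library and 11.9% (10.3 to 13.6, 180 of 1512) of the Ldlr-/- HFD library had UMIs of at least 2 G2 and M phase genes. Adventitial-like cells were at 8.70% (7.88 to 9.58) and 12.2% (10.4 to 14.1), but at Leiden resolution 2 those of the Ldlr-/- HFD library were at 9.26%, within the C57BL/6 interval. Intimal-like cells were at 9.17% (4.49 to 16.2, 10 of 109) and 7.69% (3.38 to 14.6, 8 of 104), a difference not detectable at this number of cells. With at least 3 genes asked for, the share of the Ldlr-/- HFD library was 1.92%, while that of the C57BL/6 library stayed within its interval. Conventional dendritic cell-like cells were at 15.6% (8.77 to 24.7) and 14.9% (7.40 to 25.7), and lymphoid-like cells were 4 of 10 and 33 of 188 (17.6%). As background, non-leukocyte-like cells were at 1.61% (1 of 62, median 10424 UMIs) and 1.87% (2 of 107, median 6626 UMIs), against medians of 6596 and 7307 UMIs in macrophage-like cells. Without thinning the shares were 19.7% and 26.2% in macrophage-like, 19.3% and 23.5% in adventitial-like, 23.1% and 37.96% in intimal-like and 43.5% and 53.6% in dendritic cells. Thinning left out 552 and 244 shallower macrophage-like cells, and cluster 12 held 116 of the 447 and 48 of the 180 cycling cells. Cluster 12 was led by cell cycle genes such as Top2a and Mki67, without a macrophage marker among its 10 highest genes. It counted as adventitial-like at a marker mean of -0.88, near the limit of -1. At Leiden resolution 2 a cluster led by Top2a (1 and 40 cells, at -1.24) was other macrophage-like. The cycling shares of the subsets therefore depend on this naming.

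Dendritic cells were compared to ask whether other antigen-presenting cells differed in the same way. Conventional dendritic cell-like cells numbered 92 (clusters 18a, 19a, 19b and 19c) and 69 (18b, 19d and 19c), again nearly without shared clusters. NF-kB genes were lower in the Ldlr-/- HFD library for 14 of 18 (median -1.70, percentile 0), with Cxcl1 at least 20.5-fold, Il1b 5.58-fold and Ccl3 4.54-fold lower, as were 10 of 12 MHC class II genes (-0.60, percentile 0.09), such as H2-DMa (1.97) and H2-Ob (1.91), and 23 of 24 dissociation genes (-0.89, percentile 0). Interferon genes stood higher for 14 of 16 (0.88, percentile 91.2), with the RNA sensor Ddx58 14.1-fold, Oasl2 3.43-fold and Stat1 2.88-fold higher. G2 and M phase genes were lower for 12 of 15 (-1.20, percentile 0), such as Birc5 (3.74) and Mki67 (3.37). Only these 15 of the list's 28 genes had enough UMIs. The cycling shares did not differ in this way, at 15.6% and 14.9% after thinning and 43.5% and 53.6% without it. The highest ratios were those of the transcription factor Maf (12.1), Spred1 (9.29), Myof (8.23), Bcas3 (7.86) and Wwp1 (7.80), and the lowest those of the phosphatase Dusp2 (16.2-fold lower), Gadd45b (8.19), Ier3 (6.02), Ppp1r15a (6.00) and Il1b. Maf was also a leading gene of adventitial-like cluster 2. With at least 300 UMIs, 1 of the 5 highest and 3 of the 5 lowest stayed.

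The median over all genes in these dendritic cells was 0.46, and macrophage transcripts were higher, with C1qa, C1qb and C1qc summing to 2462 and 4109 CPM. Sub-cluster 19d, with the highest level of macrophage markers among the dendritic sub-clusters, may supply part of these transcripts, which was not tested. Efferocytosis (1.23, percentile 99.5), lipid uptake (1.04, percentile 97.9) and complement genes (0.92, percentile 99.1) stood above the central 95% of random lists. Efflux (0.82, percentile 88.3), proteinases (0.71, percentile 71.4), the foamy list (0.57, percentile 92.6), lysosome genes (0.57, percentile 97.2) and the interferon genes above stood within it. Single genes of these lists included Axl 4.53-fold, Stab1 4.32-fold, C1qc 2.78-fold and Trem2 2.12-fold higher. Mitochondrial transcripts stood at 0.76 (percentile 99.95) and glycolysis at -0.24 (percentile 0.61). Cholesterol synthesis (-0.13, percentile 0.29) and S phase (-0.17, percentile 0.06) stood at 0.43 and 0.46 with every cell thinned. Oxidative phosphorylation (0.18, percentile 85.2) and chemokine genes (0.46, percentile 79.6) turned to -0.32 and -0.04 with TMM, which shifts this comparison by -0.50.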

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

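The tests of lowest barcode and of doublets for lymphoid-like cells and of a library-wide source for long genes were chosen after the result was seen, and the other tests before.

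Several signals lay in cells or genes that no comparison of the report uses and stood above their level in the C57BL/6 library. Sub-cluster 11g, which stayed unnamed, held 37 cells or 1.64% (1.16 to 2.26) of the Ldlr-/- HFD library and 0 of the other, a limit of 0.0514%. It carried S100a8 at 829 CPM and S100a9 at 853 CPM together with C1qa at 3860 CPM, at a median of 14229 UMIs. Among genes left out of the ranking by their names, Gm15655 was at 75.2 CPM in macrophage-like cells of the Ldlr-/- HFD library against 1.08 in the C57BL/6 library, Gm15648 at 14.7 against 0.436 and Gm26722 at 6.94 against 0.308.

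Dissociation and immediate early genes were lower in macrophage-like cells of the Ldlr-/- HFD library. The list's median was -1.69 with every cell thinned, but this does not decide on depth per cell as the cause. Random thinning keeps each gene's expected share of a cell's UMIs, so it could hardly have moved this ratio. Handling of the whole library during digestion and sorting is in line with the data: the list was also lower in conventional dendritic cell-like cells (-0.89), non-leukocyte-like cells (-1.72), fibroblast-like cells (-1.48) and smooth muscle-like cells (-1.91). The NF-kB and cytokine genes of the report, also lower in dendritic cell-like cells (-1.70), may partly share this source, for which no test was set. Genotype, diet, age and tamoxifen remain open and untested.

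Long genes were higher in the Ldlr-/- HFD library, the longest above the shortest by 0.73 in macrophage-like cells. A source acting on the whole library is in line with the data, as this difference was also 0.99 in conventional dendritic cell-like cells and 0.70 in non-leukocyte-like cells, but this does not separate preparation or counting from genotype or diet acting on all cells. The record names the same kit for both libraries, but not whether both were counted alike, with or without introns, and a difference there may have raised long genes such as Ptprb and Cacna1a. Damaged cells cannot be told apart from other sources: without cells above 5% mitochondrial UMIs, the log2 ratio of the nuclear RNA Malat1 was 0.43 against 0.49 with them, between the values that would have decided it. The test used Malat1 only and did not measure the length difference without those cells. Neat1 was lower in the Ldlr-/- HFD library (-0.22, and -0.29 without them). Meg3, at 0.359 and 1.12 CPM, was higher (1.64, and 1.65 without them). Genotype, diet, age and tamoxifen remain open and untested.

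Lymphoid-like cells were few in the C57BL/6 library. A higher cut on UMIs per barcode there is argued against, since its lowest barcode had 1601 UMIs, against 2056 in the Ldlr-/- HFD library. Doublets with macrophages are argued against as the whole cause, since lymphoid-like clusters 14d and 20, with the lowest levels of macrophage markers (-3.27 and -3.48), alone made up 4.12% (3.34 to 5.03, 93 cells) of the Ldlr-/- HFD library, above the 0.359% upper bound of the C57BL/6 share. The sort, the trimming of tissue around the aorta, genotype, diet and age remain open and untested.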

How the results depend on the processing

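The alternatives that leave out cells of over 2 times the median UMIs or the sub-clusters of cluster 11, that lower the adventitial threshold to -1.5, and that remove the gene length trend were chosen after seeing the data. No paired analysis was possible because each group is 1 pooled library. Of 120 alternative values of shares, 87 lay within the 95% interval of the reported value and 33 moved outside it. Of 737 list medians between libraries, 683 lay within it, 40 moved and 14 reversed, and of 326 between subsets, 308, 16 and 2. Of 60 cycling shares, 41 lay within and 19 moved. Of 2890 values of named genes, 2322 lay within, 551 moved and 17 reversed. List medians from 5 UMIs all lay within their intervals. The intimal-like and dendritic comparisons rest on the fewest cells, 121 and 108 and 92 and 69. Below, each value stands under its alternative, with the libraries as C57BL/6 and HFD, shares in %, and lists and genes as log2 ratios. The cause was not tested unless the alternative itself removes the cells or genes concerned.

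Leiden resolution 2 gave adventitial-like 92.8 and other macrophage-like 5.05 (C57BL/6), adventitial-like S phase 0.13, G2 and M phase -1.09, Cenpe -0.094, Prc1 -0.74, Ckap2 -0.10 and Top2a -0.39, intimal over adventitial in HFD S phase -0.20 and G2 and M phase -0.20, and adventitial-like cycling 9.26 (HFD). With each library clustered alone, C57BL/6 shares were macrophage-like 85.2, lymphoid-like 0, monocyte-like 0, mast cell-like 0.240, adventitial-like 90.03 and other macrophage-like 7.66, and HFD shares were lymphoid-like 6.65 and monocyte-like 1.02. That C57BL/6 macrophage-like share lacks 2 clusters that stayed unnamed. The larger cluster, with 608 cells, lost the name adventitial-like over 1 neutrophil marker. The smaller, with 67 cells, was led by Ear2 and Fn1, as cluster 15 of the main clustering was. With each library clustered alone, adventitial-like G2 and M phase was 0.33, dendritic cholesterol synthesis 0.060 and S phase 0.078, and intimal over adventitial proteinases in HFD -0.072. With lipid and lysosome lists left out of the variable genes, HFD shares were lymphoid-like 6.70, monocyte-like 1.11, intimal-like 7.91, adventitial-like 87.6 and other macrophage-like 4.52, C57BL/6 shares were adventitial-like 88.9 and other macrophage-like 8.93, and intimal-like NF-kB was -0.55 and dissociation -1.09.

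TMM scaling moved every ratio by its shift. In macrophage-like cells it gave cholesterol synthesis -0.96, lysosome -0.61, interferon -0.77, MHC class II -0.26, G2 and M phase -0.046, glycolysis -0.77, oxidative phosphorylation -0.20, mitochondrial transcripts 0.23, chemokine receptors -0.17 and Uqcrq -0.015. In adventitial-like cells it gave lysosome -0.77, NF-kB -2.84, interferon -0.69, MHC class II -0.39, G2 and M phase 0.071, glycolysis -0.92, oxidative phosphorylation -0.27, mitochondrial transcripts 0.20, Ctss -0.0070, Ndufa4 -0.037 and Cox6c -0.0059. In dendritic cells it gave efflux 0.32, foamy 0.068, NF-kB -2.20, MHC class II -1.10, glycolysis -0.74, oxidative phosphorylation -0.32, mitochondrial transcripts 0.26, Atp5g1 -0.10 and Ndufv3 -0.043.

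With every cell thinned, intimal-like S phase was 0.095, G2 and M phase 1.26 and Mcm6 0.17, and dendritic efflux 0.28, cholesterol synthesis 0.43 and S phase 0.46. Intimal over adventitial was then -0.13 for G2 and M phase and 0.076 for Arhgap23 in C57BL/6, and 0.017 for cholesterol synthesis and -0.99 for G2 and M phase in HFD. Means over cells gave intimal-like S phase 0.11, and intimal over adventitial in HFD S phase -0.054 and G2 and M phase -1.36. Without removal by Scrublet score, G2 and M phase was 0.30 in intimal-like cells and -1.25 for intimal over adventitial in HFD. The stricter cell filter gave non-leukocyte-like 0.729 (C57BL/6) and 4.44 (HFD).

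The adventitial threshold of -1.5 gave adventitial-like 97.8 and 87.1 and other macrophage-like 0.0354 and 6.72. Without cells of over 2 times the median UMIs, macrophage-like was 97.4 and 80.4, dendritic 1.23 and 2.05, non-leukocyte-like 0.871 (C57BL/6), and in HFD intimal-like 3.79, adventitial-like 87.5 and other macrophage-like 8.76. Without the sub-clusters of cluster 11, HFD shares were intimal-like 2.20 and adventitial-like 86.2, and Mmp8 in macrophage-like cells was -1.29. In intimal-like cells foamy was then -0.062, lysosome -0.15, MHC class II -0.11, S phase 0.22, G2 and M phase 1.11, oxidative phosphorylation 0.052, Mcm6 0.26, Gla -0.46, Ndufa4 -0.48 and Ctsd -0.58. Intimal over adventitial in HFD was foamy 0.11, lysosome 0.042, MHC class II 1.77, S phase 0.24, G2 and M phase -0.057, dissociation -0.52 and oxidative phosphorylation -0.090. With the gene length trend removed, oxidative phosphorylation was 0.49 in macrophage-like, 0.78 in intimal-like, 0.46 in adventitial-like and 0.56 in dendritic cells, and mitochondrial transcripts 1.02, 0.98, 1.00 and 1.29. Intimal-like dissociation was then -1.15 and dendritic S phase 0.083.

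Cycling shares by at least 3 genes were 3.38 and 5.29 in macrophage-like, 3.37 and 5.83 in adventitial-like, 1.92 in intimal-like (HFD) and 5.97 in dendritic cells (HFD). By at least 1 UMI of Mki67 or Top2a they were 7.18 and 9.59 in macrophage-like and 6.80 and 9.20 in adventitial-like cells. Unthinned they were 19.7 and 26.2 in macrophage-like, 23.1 and 37.96 in intimal-like, 19.3 and 23.5 in adventitial-like and 43.5 and 53.6 in dendritic cells, as deeper cells give more UMIs of any gene.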

Other observations

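Some genes that ranked high in macrophage-like cells of the Ldlr-/- HFD library were also found in its other classes. Ptprb was at 80.7 CPM (76.1 to 85.5) in macrophage-like, 86.3 (68.9 to 107) in conventional dendritic cell-like and 89.8 (77.3 to 104) in lymphoid-like cells of that library, and at 117 in fibroblast-like and 2421 in endothelial-like cells. In the C57BL/6 library it was at 0.539, 0.945, 0 (12 cells, a limit of 30.3), 21.2 and 629 CPM in the same order. Cacna1a was higher in macrophage-like cells of the Ldlr-/- HFD library, at 86.3 CPM (81.6 to 91.3), than in its dendritic (46.3, 33.7 to 61.9) and lymphoid-like cells (47.9, 38.8 to 58.4), against 1.62 CPM in macrophage-like cells of the C57BL/6 library and 0 UMIs in its dendritic (a limit of 2.84 CPM) and lymphoid-like cells (30.3). In fibroblast-like cells Cacna1a was at 25.4 CPM (9.32 to 55.3) in the C57BL/6 library and 41.2 (24.8 to 64.4) in the other. Hspb7, a small heat shock protein, was at 13.5, 15.4 and 13.8 CPM in macrophage-like, dendritic and lymphoid-like cells of the Ldlr-/- HFD library, and at 59.3 CPM in fibroblast-like cells of the C57BL/6 library and 30.4 in those of the other. Gpnmb differed between classes there, at 180 CPM in macrophage-like, 15.4 in dendritic and 19.3 in lymphoid-like cells.

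Sub-cluster 14e, part of the T cell-like cells, held 4 cells of the C57BL/6 library and 17 of the Ldlr-/- HFD library, and carried Dntt, a gene of immature lymphocytes, at 1645 and 423 CPM. Its cells had a median of 20549 UMIs in the Ldlr-/- HFD library.

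Some Gm-named genes, left out of the ranking, were far lower in macrophage-like cells of the Ldlr-/- HFD library: Gm17056 was at 117 CPM in the C57BL/6 library and 1.26 in the other, Gm7676 at 7.18 and 0.0701, and Gm20481 at 7.47 and 0.140.

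Haemoglobin transcripts stood higher in the C57BL/6 library. In macrophage-like cells Hbb-bs was at 110 CPM there, with a UMI in 4.62% of cells, and at 0.350 CPM in the Ldlr-/- HFD library. Hba-a1 was at 54.4 and 0.420 CPM, Hba-a2 at 48.8 and 0.280 CPM, and Hbb-bt at 18.2 CPM and 0 UMIs, a limit of 0.210 CPM. The nuclear RNA Malat1 was at 35213 and 49569 CPM and Neat1 at 830 and 713 CPM. In lymphoid-like cells, C1qa, C1qb and C1qc of macrophages summed to 5169 and 6199 CPM, and in endothelial-like cells to 1510 and 795 CPM. Collagen transcripts of fibroblasts, as the sum of Col1a1, Col1a2, Col3a1 and Dcn, were at 26.1 and 92.3 CPM in macrophage-like cells.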
